A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

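ATAC-seq libraries of 10 samples were described in the labels: human satellite cells fresh (2) and after 12 days of culture (3), and mouse satellite cells fresh (1) and after 4 (2) and 10 (2) days. Groups and replicate numbers were taken from the sample titles. Cells came from collagenase and dispase digestion, were sorted and grown at 5% oxygen, per the labels' protocols; the human medium held 500 nM dexamethasone and the mouse medium none. Per the submitters' processing notes the tools were Bowtie2, MACS2, bedtools and DESeq2 and the builds hg38 and mm10, with no versions; the role and settings of each tool are not given in the sources used here.

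The authors deposited 1 table of all loci and 1 of selected loci for each species. Per the file headers, each locus has a mean normalized count, here treated as a signal averaged over the authors' libraries, a log2 fold change with its standard error on the log2 scale, a Wald score, a p-value and an adjusted p-value. All loci numbered 294855 in human and 239543 in mouse, each 100 bp wide; starts were read as counting from 0 and are printed counting from 1. Adjusted p-values were deposited for 197634 human and 197742 mouse loci, those with a mean of at least 6.58 and 7.51, and loci without one were left out. The score equalled the fold change over its standard error, and the adjusted p-values equalled the Benjamini-Hochberg values computed from the deposited p-values to within 1.5e-15. The selected loci were those with an adjusted p under 0.01 and an absolute log2 fold change over 3, 44478 in human and 37426 in mouse, except for 1 mouse locus whose adjusted p was not under 0.01. No column holds values of a library, so total reads per library are unknown, and no replicate spread, left-out library, other normalization or other test could be computed; the fixed design had planned tests on counts, and the authors' own comparison is described in their place.

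The headers do not say which group a positive log2 fold change stands for, and the sign was worked out from the values. In a negative binomial Wald fit a locus with reads in 1 arm alone and dispersion at its upper limit has a standard error set by the number of libraries per arm. In human, loci with positive log2 fold changes at this plateau had a median standard error of 4.4123, against 4.4075 computed for reads in the arm of 3 alone and 4.3281 for the arm of 2; for negative ones the median was 4.3294. Positive human values were therefore read as higher in cultured cells. In mouse, the largest standard error was 4.562, against 4.5622 computed for arms of 2 and 3 libraries, 5.5875 for 1 and 4 and 3.817 for 3 and 4. The mean normalized counts of weak loci were sums of whole multiples of 7 step sizes, read as 1 per library. Of these, 3 moved the fold change up (0.0223, 0.0672 and 0.0931 normalized counts per read), 2 moved it down (0.204 and 0.382) and 2 did not move it (0.267 and 0.284). The fresh mouse sample is titled replicate 3 and both cultured times have 2 libraries, so the arm of 3 was read as fresh, positive mouse values as higher in fresh cells, and all mouse values were multiplied by -1 in the text. By this reading 2 fresh libraries of the authors' fit were not among the samples analysed here, and the fold change concerns 1 of the 2 culture times although the title of the table names both. If the reading is wrong, higher and lower change places. A read counted for less in the 3 fresh libraries than in the 2 cultured ones, a difference in relative depth that goes with the groups.

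Directions are given as cultured against fresh. Calls were made at the limits of the selected loci, on autosomes alone, because the sex of donors and animals was not used. Human loci were given to the protein-coding gene of RefSeq (GRCh38.p14) whose body holds their midpoint, or else to the nearest gene edge within 50 kb; the table used here has no strand, so start and end of a gene were not told apart and exons were not distinguished. Of the autosomal tested loci, 148705 (78.0%) were assigned, to 16989 genes. Of 350 genes in 19 lists fixed before the data were examined, 336 had a tested locus. CKM, DES, DUSP1, EGR2, FOXO1, FOXO3, NOTCH3, PGK1 and RGS5 are each in 2 lists. As a check of the build, 29.8% of the 38143 human loci with the highest means lay within 1 kb of a gene edge, against 3.92% after a shift by 10000 bp. No mouse annotation was used here, so mouse loci are given by position.

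Lists were tested with the preranked form of camera in limma 3.58.1 (R 4.3.3), two-sided, on the mean Wald score of a gene's loci, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists, called under 0.05. An estimated correlation needs values per library and was not computed. Loci of a gene are not independent, and a mean over many loci varies less than 1 locus; as a second test each list was set against 10000 random lists of genes with a like number of loci. In the text, a locus is named by a rule fixed in advance: per direction the 10 loci with the largest absolute log2 fold change among called autosomal loci with a mean at or above the median, 1 per named gene in human; 12 fixed genes at all loci and at the locus with the highest mean; and up to 4 members per list with the smallest p, taken over a gene's loci because no p per gene was had. The condition of the rule that all fresh libraries lie on 1 side of all cultured ones could not be applied, nor its parts on genes changed in both species and on 10 against 4 days. Windows of 100 kb (outside the dense windows described below), runs of loci and other genes of the lists were chosen after their values were seen.

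Alternatives planned before the data were examined and run were an adjusted p under 0.05 with no fold limit, all chromosomes, and the list test on the locus with the highest mean of each gene. Alternatives chosen after seeing the data centred the fold changes on their median, on their trend with the mean count (50 bins) or on strong loci at gene edges, with p-values recomputed from the deposited standard errors, or left out windows of 200 kb with at least 100 loci and loci with means over 100000, or loci under the median mean. Steps over all loci were tested on simulated data, with 200 human loci changed by a log2 of 8 among 197634 and a common shift of -0.8. Centring on the median called 198 with their sign and 2 unchanged loci, and in mouse 199 of 200 and 3 of 197742. The changed loci were few, of both signs at random and of small standard error, while in the data calls were many and mostly higher. The simulation therefore does not show how centring behaves on such data, and centring on gene edges was not simulated. The camera step called a list of 25 genes shifted by 1 SD in 93 of 100 draws over 16989 genes, and other lists 5 times over all draws. In these draws genes were independent and of equal spread, while in the data the spread of a gene's mean depends on its number of loci. The draws therefore do not show how often camera calls lists falsely on these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.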

Results

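Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in satellite cells of human and mouse skeletal muscle. Satellite cells are the stem cells of muscle fibres, and in culture they proliferate as myoblasts. The labels describe 10 libraries. The 5 human libraries, from the vastus lateralis, were 2 of freshly isolated cells and 3 of myoblasts after 12 days of culture. The 5 mouse libraries, from whole hindlimb, were 1 of fresh cells, 2 after 4 days and 2 after 10 days of culture. Fresh human libraries were made from 5000 to 10000 cells and all others from 50000 cells, per the labels. Cell input thus went with the human groups, and its effect on direction and position of calls cannot be separated from that of culture. The labels do not say which libraries shared a donor or animal, so the p-values describe only the spread between these libraries, which may be partly technical. Values per library were not analysed here. Each species had a table in which the authors compared fresh with cultured cells at loci of 100 bp, and total reads per library are unknown.

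The human comparison asked which loci were more or less open after 12 days of culture than in fresh cells. Of 190715 autosomal loci with an adjusted p, 32117 were called higher in cultured cells and 11078 lower, at an adjusted p under 0.01 in the authors' Wald test and an absolute log2 fold change over 3. Loci called higher had a median log2 fold change of 5.70, with an interquartile range of 4.59 to 7.19. Loci called lower had a median of -4.75, with an interquartile range of -5.91 to -3.88. Gene edges, the 1 kb around the start or end of a protein-coding gene, held 2.98% of loci called higher, 20.7% of those called lower and 17.6% of loci not called. Against loci not called, the odds ratio of lying at a gene edge was 0.144 for loci called higher and 1.23 for loci called lower, the second with a Fisher exact p of 1.13e-16 in which loci are not replicates. Among the 38143 loci with the highest mean counts the odds ratio for loci called lower was 0.698, on the other side of 1. Gene bodies away from their edges held 48.6% of loci called higher and 39.7% of those called lower. The split between directions depended on the scale and the limits. On the authors' scale 74.4% of calls were higher in cultured cells, the group with the larger cell input. The share was 65.2% at an adjusted p under 0.05 with no fold limit and 66.8% with the trend against the mean count removed. It was 81.4% with the median of all loci centred on 0, and 90.3% with strong loci at gene edges, whose median log2 fold change was -1.17, centred on 0. The median of all tested loci was -0.40.

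**Figure D1:**
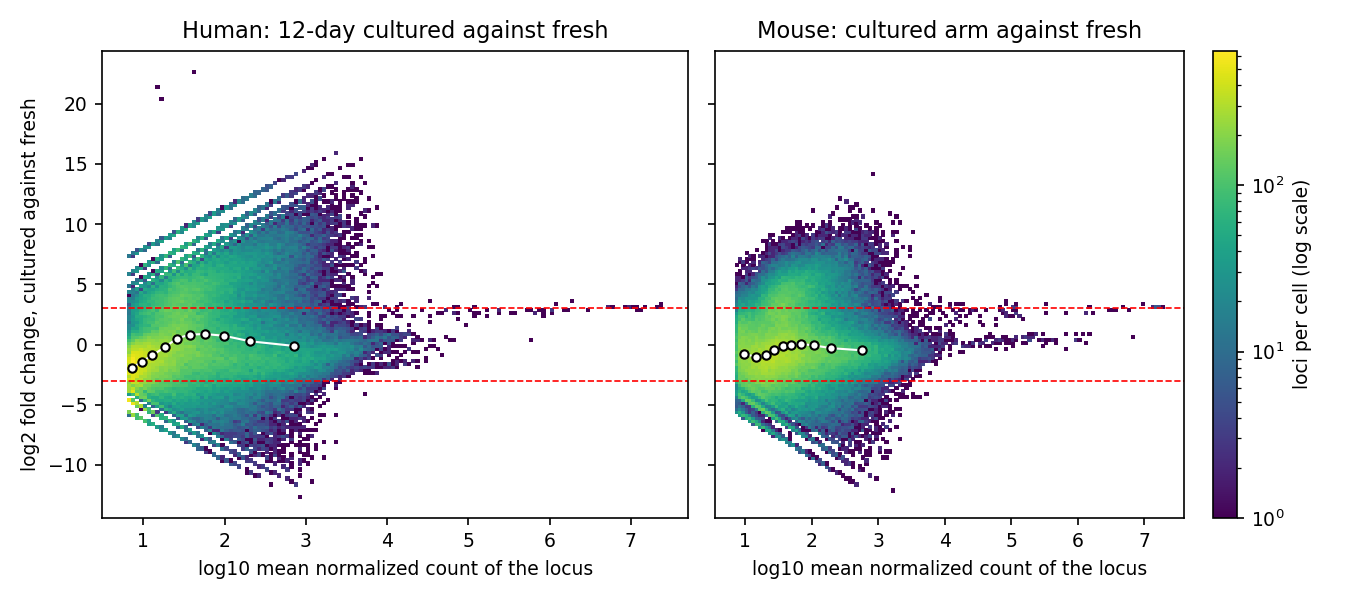
Log2 fold change, cultured against fresh, of autosomal loci against the log10 of their mean normalized count, in human (left) and mouse (right); colour gives the number of loci on a log scale, dashed lines the fold change limit of 3, and white points the medians of 10 bins of loci by mean. In human the medians ran from -1.92 in the lowest bin up to 0.87 in bin 7 and -0.11 in the highest.

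Immediate early and stress genes, which are induced within minutes of stimulation or injury, had more loci called lower in culture than called higher. All 23 members of the list had tested loci. Of their 697 loci, 141 were called lower, 33 higher and 523 were not called; adjusted over the list alone the counts were 143 and 35. In limma's camera test on the mean Wald statistic of each gene's loci the list was called lower, with an adjusted p of 0.000248 over 19 lists; its mean statistic was -1.54, against 0.14 over all genes. Loci called lower outnumbered those called higher under each centring of the fold changes, by 71 to 55 at the least. FOSB, a subunit of the transcription factor AP-1, had 23 of 35 loci called lower and none higher, with a median log2 fold change of -5.16. FOS, another AP-1 subunit, had 16 of 49 lower and 1 higher, and EGR1, an early growth response factor, 15 of 46 lower and none higher. NR4A1, an orphan nuclear receptor, had 11 of 64 lower, and the heat shock genes HSPA1A and HSPA1B had 8 of 18 and 12 of 41. Of the 23 members, 15 had more loci lower than higher and 7 more higher than lower. Among the 7, JUN had 7 of 31 loci higher and 2 lower, IER5 9 of 50 and 2, KLF6 2 of 28 and none, and KLF2, NR4A2, MYC and IER3 each 1 higher and none lower. KLF4 had 2 of each. Among these genes the median log2 fold change over loci was above 0 at JUN (0.39) and IER5 (1.28). It was below 0 at KLF6 (-0.48), KLF2 (-0.46), NR4A2 (-0.78), MYC (-1.81), IER3 (-2.11) and KLF4 (-2.72). At each of the 7 the gene's smallest p was at a higher locus away from the gene. It was at 25219 bp from JUN, 47056 bp from IER5 and 40219 bp from KLF6. For NR4A2, MYC, IER3 and KLF2 it was at 23506, 13620, 15196 and 10414 bp. The 2 lower loci of JUN lay inside the gene, with -3.96 ± 0.98 and -6.15 ± 1.02 in the authors' deposited table. Some lower loci were remote too, with that of ATF3 of smallest p at 25281 bp. At the locus with the smallest p of the whole list, inside EGR1 at chromosome 5, 138465732 to 138465831, the log2 fold change was -6.21 ± 0.84 (SE) with an adjusted Wald p of 1.02e-11 in the authors' deposited table. For NR4A1 it was -7.85 ± 1.10 inside the gene at chromosome 12, 52043438 to 52043537, in the authors' deposited table. Beside this direction stand single loci that rose, with 8.64 ± 1.19 at 11171 bp from DUSP1 and 6.90 ± 0.97 at 11273 bp from KLF4 in the authors' deposited table. All coordinates are of hg38 in human and mm10 in mouse.

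Genes of satellite cell quiescence moved in both directions. All 25 members had tested loci. Of these 502 loci, 72 were called higher in culture, 53 lower and 377 were not called, with 73 and 54 adjusted over the list alone. At the rates of all tested loci of like position relative to genes and like mean count, 90.8 higher and 29.8 lower would be called. The balance depended on the scale, with 68 higher and 67 lower with the trend against the mean count removed, 85 and 43 with the median centred on 0 and 111 and 26 with gene edges centred on 0. The camera adjusted p was 0.841. The median over loci was -0.46 while the mean gene statistic was 0.07, so these 2 summaries differed in sign. CALCR, the calcitonin receptor, had 6 of 11 loci lower and 2 higher. CXCR4, a chemokine receptor, had 7 of 13 lower, CHRDL2 had 6 of 16 lower, and both loci of CDKN1B, an inhibitor of cyclin-dependent kinases, were lower. FOXO1, a forkhead transcription factor, had 7 of 35 lower and 1 higher. PAX7, the transcription factor that defines satellite cells, had 9 of 31 loci higher and 2 lower, VCAM1 3 of 4 higher, and CAV1, a caveolin, 8 of 28 higher. Several of the higher loci of PAX7 were neighbours, at chromosome 1, 18693511 to 18694003 and 18711674 to 18712625. Near an edge of PAX7, loci starting at 18630901, 18631066 and 18631233 had -1.60 ± 1.14, -1.28 ± 1.11 and -2.37 ± 1.05, none called. The smallest p values of the list lay at loci higher in culture. In the authors' deposited table the log2 fold change was 9.52 ± 1.01 inside TEK, 8.65 ± 1.03 at 19053 bp from PAX3, 9.28 ± 1.11 inside RGS5, which is also in the list of smooth muscle and pericyte markers, and 9.62 ± 1.16 at 8735 bp from CAV1.

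Genes of myogenic commitment, which encode regulators and structural proteins of differentiating muscle, and genes of the Notch pathway were not called as lists. The 27 myogenic genes had 294 loci, 46 higher and 22 lower, with 46 and 23 adjusted over the list alone and a camera adjusted p of 0.566. At the rates of loci of like position and mean count, 52.1 higher and 18.4 lower would be called. With the trend removed the counts were 41 and 30, and with gene edges centred 66 and 5. Their median over loci was -0.17, against a mean gene statistic of 0.54. Loci with the smallest p were higher in culture: 10.08 ± 1.06 inside TTN, the giant protein titin, 9.19 ± 0.99 at 14276 bp from CHRNA1, a subunit of the acetylcholine receptor, 8.35 ± 1.03 at 15183 bp from ACTC1 and 8.42 ± 1.10 at 10636 bp from CDH2, in the authors' deposited table. The 18 Notch genes had 416 loci, 72 higher and 32 lower, with the same counts adjusted over the list alone and a camera adjusted p of 0.566. Position and mean count would give 67.4 and 21.9. The counts were 61 and 44 with the trend removed and 97 and 9 with gene edges centred. Against the balance of calls, the median over loci of the Notch genes was -0.84 and their mean gene statistic -0.28. MAML2, a coactivator of Notch, held 34 of the 72, out of 56 loci, and none of its loci were lower. NOTCH2 had 10 of 32 loci lower and 1 higher. Inside MAML3 and RBPJ, the DNA-binding partner of Notch, the authors' deposited table gave log2 fold changes of 8.28 ± 0.85 and 8.21 ± 0.88, and inside LFNG 5.56 ± 0.80.

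Markers of other cell types were looked at in the same way. The 12 immune markers with loci had 22 of 73 loci higher in culture and 1 lower, with 24 and 2 adjusted over the list alone. Camera called this list higher at an adjusted p of 0.044, with a mean statistic of 1.58. In this mean CD3E counts as much as any other gene, by a single locus with a large score. The list was not tested without CD3E, so how far the call rests on that locus is not known. On the locus with the highest mean count of each gene the adjusted p was 0.122, and over all alternatives it ranged from 0.0104 to 0.122. PTPRC, the pan-leukocyte antigen CD45, had 7 of 12 loci higher, CSF1R, the receptor of macrophage colony-stimulating factor, 6 of 10, LAPTM5 5 of 19 with 1 lower, CX3CR1 3 of 8, and the single locus of CD3E was higher. The authors' deposited table gave 12.07 ± 0.99 at 19307 bp from PTPRC, at chromosome 1, 198776734 to 198776833, and 10.32 ± 0.87 at 652 bp from CD3E. No locus of CD68, CD14, SPI1, ITGAM, CORO1A, CCR2 or IRF8 was called. Fibro-adipogenic markers had 35 of 167 loci higher and 6 lower, with 35 and 7 adjusted over the list alone and a camera adjusted p of 0.235. Position and mean count would give 33.5 and 10.4, so the count of higher loci was near that of like loci. At 32835 bp from CD55 and 32098 bp from DPP4 the authors' deposited table gave 11.06 ± 1.08 and 10.15 ± 1.08, and inside COL14A1, a fibril-associated collagen, 7.19 ± 0.87. Endothelial markers had 17 of 119 loci higher and 7 lower, smooth muscle and pericyte markers 12 of 103 and 6, Schwann cell markers 4 of 42 and 6, and myofibre markers 7 of 44 and 2. Their camera adjusted p values were 0.566, 0.643, 0.643 and 0.643, and adjusted over the list alone the counts higher and lower were 17 and 7, 12 and 6, 4 and 6, and 6 and 1. With the trend removed the counts were 21 and 4 for immune, 32 and 10 for fibro-adipogenic, 18 and 9 for endothelial, 11 and 10 for smooth muscle and pericyte and 6 and 2 for myofibre markers. With gene edges centred they were 29 and 0, 46 and 5, 34 and 4, 15 and 5, and 9 and 1. Single loci of these lists differed in sign: EGFL7 had -10.68 ± 1.49 and PECAM1 6.69 ± 1.00 in the authors' deposited table, and MYH11 had 9.14 ± 1.42 and ACTA2 -5.52 ± 0.95 there. Of the Schwann cell markers EGR2, which is also in the immediate early list, held 15 of the 42 loci, with 4 of the 6 lower and 1 of the 4 higher. NGFR, another of them, had -5.44 ± 1.12 at 5 bp from the gene, and MYH4, a fast myosin, 6.66 ± 1.23 at 2504 bp in the authors' deposited table.

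Extracellular matrix genes had 138 of 740 loci higher and 53 lower, with 139 and 55 adjusted over the list alone and a camera adjusted p of 0.566. Position and mean count would give 139.8 and 45.2. The counts were 107 and 62 with the trend removed and 191 and 28 with gene edges centred. Their loci with the smallest p were inside COL15A1 and MMP2, a gelatinase, with 9.24 ± 0.87 and 12.86 ± 1.33 in the authors' deposited table. TGF-beta and BMP genes had 72 of 530 loci higher and 45 lower (72 and 45 adjusted over the list alone), and WNT genes 54 of 337 higher and 13 lower (53 and 13), with camera adjusted p values of 0.566 and 0.643. Position and mean count would give 95.1 and 32.1 calls for TGF-beta and BMP genes, and 49.9 and 17.9 for WNT genes. TGF-beta and BMP genes had a median over loci of -0.51 and a mean gene statistic of -0.23, and WNT genes -0.26 and 0.40. With the trend removed TGF-beta and BMP genes had 57 higher and 55 lower and WNT genes 50 and 18, and with gene edges centred 110 and 21, and 73 and 5. Inside TCF7L2, a transcription factor of WNT signalling, the authors' deposited table gave 7.67 ± 0.80, and at 25096 bp from FZD1, a WNT receptor, 10.54 ± 1.01. At 8506 bp from LTBP2, which encodes a protein of microfibrils, it was 11.03 ± 1.39 in the authors' deposited table. Hypoxia and glycolysis genes had 29 of 198 loci higher and 18 lower, unchanged over the list alone, with an adjusted p of 0.643; inside SLC2A1, a glucose transporter, the value was 5.86 ± 0.83, and inside ADM, adrenomedullin, -7.61 ± 1.17 in the authors' deposited table. Glucocorticoid targets, whose inducer dexamethasone at 500 nM was part of the human medium, had 32 of 405 loci higher and 46 lower (32 and 45 adjusted over the list alone; adjusted p 0.219). The list was called lower on the locus with the highest mean count of each gene, at an adjusted p of 0.0314, and against random lists, at 0.0076; over the 3 centrings the adjusted p was 0.199 to 0.254. Position and mean count would give 70.9 higher and 23.3 lower loci for glucocorticoid targets. The shortfall of higher loci lay at percentile 20.5 of random lists. ZBTB16 had 16 loci higher and 2 lower, FKBP5 none and 4. SGK1 had a locus at 8.30 ± 1.10 and MT2A, a metallothionein, one at -5.92 ± 0.81 in the authors' deposited table. HOX and limb genes had 13 of 277 loci higher and 19 lower (11 and 11 adjusted over the list alone; adjusted p 0.12, but 0.00887 against random lists and 0.0672 to 0.138 under the other alternatives), with 6.52 ± 0.85 inside TBX15 and -5.65 ± 1.07 at 20859 bp from PITX1, a hindlimb factor, in the authors' deposited table. For HOX and limb genes position and mean count would give 37.0 higher and 14.1 lower. Their shortfall of higher loci lay at percentile 0.06 of random lists. Late AP-1 genes had 20 of 160 higher and 16 lower (22 and 17; adjusted p 0.569), with 8.22 ± 1.08 inside BACH2 and -7.03 ± 0.98 inside JDP2 in the authors' deposited table. Cell cycle genes had 10 of 126 loci higher and 4 lower (9 and 2; adjusted p 0.841), with 6.75 ± 1.00 at 9767 bp from RRM2, 10.78 ± 1.71 inside AURKA and -8.14 ± 1.54 at 23811 bp from CDK1 in the authors' deposited table. Constitutive genes had 9 of 113 higher and 13 lower (9 and 13; adjusted p 0.538), with -5.86 ± 0.92 inside ACTB and 6.13 ± 0.98 at 30299 bp from YWHAZ in the authors' deposited table. Which direction held more calls depended on the scale in several lists. With strong loci at gene edges centred on 0, higher and lower loci were 57 and 22 among glucocorticoid targets, 27 and 5 among HOX and limb genes, 14 and 6 among constitutive genes and 6 and 4 among Schwann cell markers. With the trend against the mean count removed, late AP-1 genes had 15 higher and 24 lower, cell cycle genes 9 and 9, and hypoxia and glycolysis genes 25 and 22; with gene edges centred these lists had 27 and 6, 19 and 1, and 35 and 5.

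**Figure D2:**
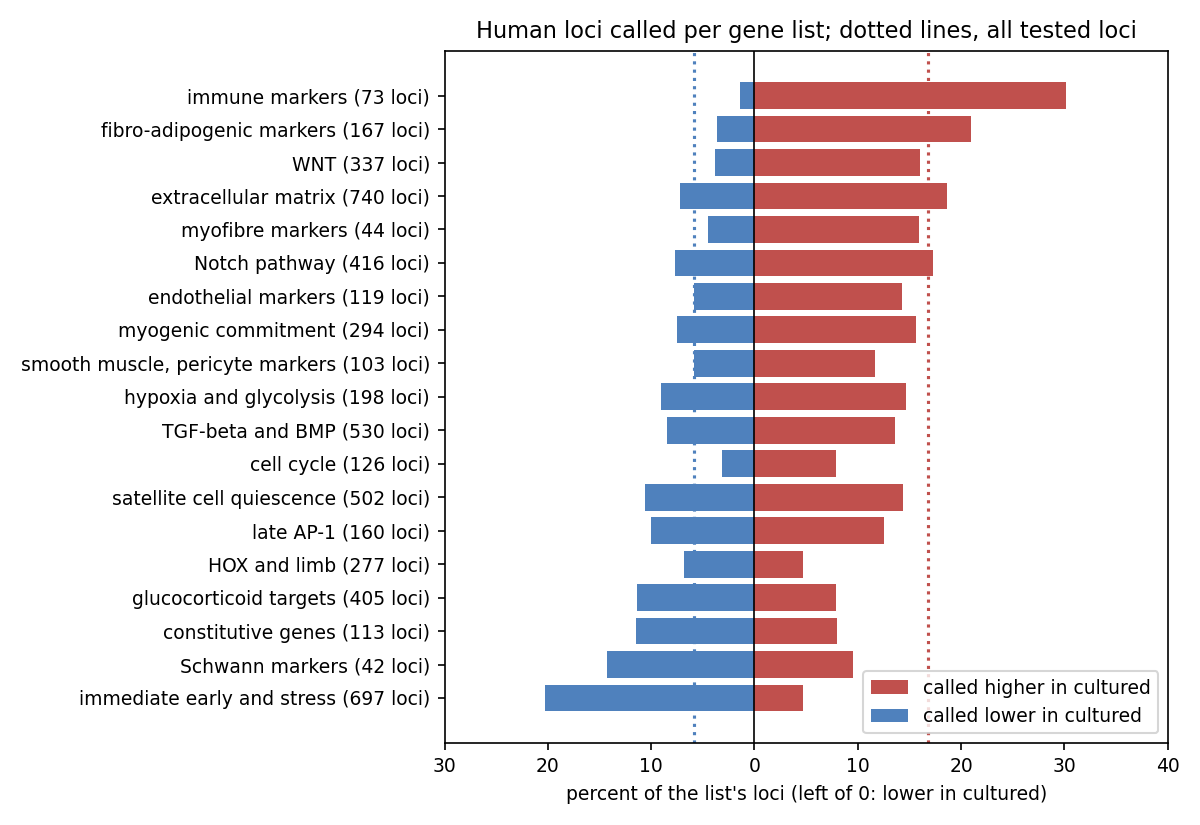
Percent of the human loci of each of 19 gene lists that were called higher (red, right of 0) or lower (blue, left of 0) in cultured cells, with dotted lines at 16.8% and 5.81%, the shares of all tested autosomal loci. Immune markers (22 of 73 loci higher) and immediate early and stress genes (141 of 697 lower) stood at the ends.

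For 12 genes fixed before the data were examined, the most accessible locus is given with all loci of the gene. It is the locus with the highest mean over both arms, which a rise in 1 arm also raises. At CALCR that locus lay 175 bp from the gene at chromosome 7, 93574850 to 93574949, with a log2 fold change of -5.95 ± 0.91 and an adjusted Wald p of 1.68e-09 in the authors' deposited table. HEYL, an effector of Notch, had -3.50 ± 0.84 at 137 bp from the gene in the authors' deposited table, with 3 of its 14 loci lower. With gene edges centred on 0 this locus had -2.33, under the limit, and 1 locus of HEYL was lower. HEY1, a related effector, had -2.02 ± 0.79 at its most accessible locus in the authors' deposited table, under the fold limit, and 3 of its 17 loci lower and 2 higher. Its 3 lower calls became 0 with fold changes centred on the median of all loci or on gene edges. PAX7 had 4.33 ± 0.91 inside the gene at chromosome 1, 18711674 to 18711773, and SPRY1, an inhibitor of growth factor signalling, 7.35 ± 1.01 at 46279 bp from the gene, in the authors' deposited table. Both passed the limits. The next loci of SPRY1 by mean were not called, with -1.12 ± 0.86, 1.92 ± 0.91 and -0.48 ± 1.18 in the authors' deposited table. SPRY1 had 2 of 20 loci higher, which became 4 with the median and 8 with gene edges centred on 0. The most accessible loci of MYF5 and MYOD1, 2 determination factors of muscle, did not pass the limits, with -0.67 ± 0.79 at 18 bp from MYF5 and 1.18 ± 0.85 at 31472 bp from MYOD1 in the authors' deposited table. MYF5 had 1 of 13 loci lower and MYOD1 2 of 19, and with the trend removed 4 and 3. MYOG, the factor of muscle differentiation, had 3 loci and none called; at 208 bp from the gene the authors' deposited table gave 8.51 ± 4.41. NOTCH3 and CCND1, which encodes cyclin D1, had no called locus among 12 and 7, except 1 higher at NOTCH3 with gene edges centred on 0, with 2.73 ± 1.07 and -0.55 ± 0.92 at the most accessible locus in the authors' deposited table. The most accessible locus of FOS, at 19653 bp from the gene, had -1.01 ± 0.76, and that of JUN, at 138 bp, -0.17 ± 0.80 in the authors' deposited table. Neither passed the limits. Near an edge of FOS itself, the locus starting at 75278563 had -2.47 ± 0.80, not called, and that at 75278831 -5.10 ± 0.85, called lower. The 16 loci of FOS called lower became 9 with gene edges centred on 0, and the 6 of CALCR 4.

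**Figure D3:**
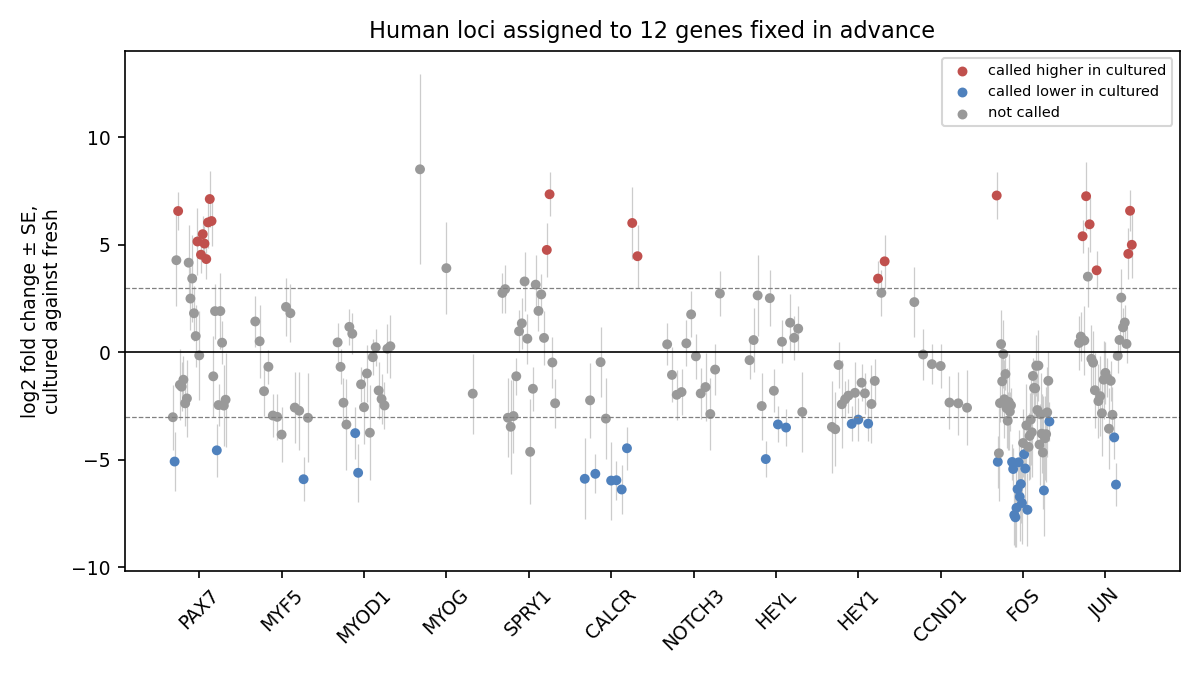
Log2 fold change, cultured against fresh, with its SE, of each human locus assigned to 12 genes fixed in advance, ordered along the chromosome within each gene; red and blue points were called higher and lower in cultured cells, grey points were not called, and dashed lines mark a log2 fold change of 3 in either direction. FOS had 16 loci lower and 1 higher, PAX7 9 higher and 2 lower.

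The loci with the largest fold changes were ranked among called loci with a mean count at or above the median. None of the 10 highest lay within 1 kb of the edge of its gene, and 1 of the 10 lowest did. In the authors' deposited table the largest was 22.60 ± 4.41, inside NRG1 (neuregulin 1) at chromosome 8, 32374320 to 32374419, a standard error near that of a locus with reads in the cultured libraries alone. The next were 15.81 ± 1.72 inside SCHIP1, 15.37 ± 1.65 inside SMYD3, 14.99 ± 1.69 inside MCM9, a DNA helicase, and 14.85 ± 1.66 inside ZMAT3 in the authors' deposited table. SGCD, which encodes delta-sarcoglycan of the muscle membrane, had 14.85 ± 1.70 inside the gene at chromosome 5, 156359593 to 156359692, in the authors' deposited table. The others of the 10 were at TMPRSS11E, APCS, CLNK and NKX2-4, between 14.19 and 14.74 in the authors' deposited table. Lower in culture, the authors' deposited table gave -11.56 ± 1.51 at 35099 bp from VSX1, -11.55 ± 1.46 at 18360 bp from CSF1, a macrophage growth factor, and -11.53 ± 1.46 inside CSMD1. At 15 bp from FAM170B it was -11.51 ± 1.46, and inside PRUNE2 -11.40 ± 1.38 in the authors' deposited table. NTN4, which encodes netrin 4, had -11.31 ± 1.46 inside the gene and IL7R, an interleukin receptor, -11.18 ± 1.46 at 9211 bp in the authors' deposited table. ZPLD1, LMNB1 and CA1 completed the 10, between -10.94 and -10.92 in the authors' deposited table. Fold changes of this size can come from loci with few or no reads in 1 arm; they depend on the authors' fit and are no bound on the difference in opening.

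The mouse table compared fresh cells with cultured cells. By its values, explained with the processing, it set an arm of 3 libraries against an arm of 2, and the 2 stand for 1 of the 2 culture times, which of them is not known here. Of 192759 autosomal loci with an adjusted p, 22026 were called higher in the cultured arm and 14473 lower, at the same limits of the authors' Wald test. Loci called higher had a median log2 fold change of 4.82 and loci called lower -4.55. Of the calls, 60.3% were higher in the cultured arm. The share was 51.6% at an adjusted p under 0.05 with no fold limit, 67.6% with the trend against the mean count removed and 72.2% with the median of all tested loci, -0.43, centred on 0. In the mouse libraries a read counted for 0.0223 to 0.0931 in the mean normalized count in the arm of 3, and for 0.204 and 0.382 in the arm of 2, so relative depth differed with the groups and cannot be separated from them. The sign of this table was worked out from its values; were it the other way, higher and lower would change places in every mouse sentence. The largest change among loci at or above the median mean count was 14.13 ± 1.40 at chromosome 17, 36767776 to 36767875, with an adjusted Wald p of 1.01e-20 in the authors' deposited table. It was followed by 12.23 ± 1.46 at chromosome 6, 91785033 to 91785132, and 11.89 ± 1.25 at chromosome 6, 140543458 to 140543557, in the authors' deposited table. Lower in the cultured arm, chromosome 2, 8112642 to 8112741, had -12.08 ± 1.53 and chromosome 9, 111473817 to 111473916, -11.59 ± 1.62 in the authors' deposited table. A pair of loci on chromosome 9, starting at 51770068 and 51770507, were both among the 10 lowest, with -11.30 ± 1.63 and -11.26 ± 1.64 in the authors' deposited table. Genes at mouse loci were not looked up, because no mouse annotation was used here.

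Windows of 100 kb were ranked by their called loci, and whether calls cluster more than chance would give was not tested. In mouse, the window of 100 kb with the most loci called higher was on chromosome 1, 20600001 to 20700000, with 28 of 65 tested loci higher and 1 lower, and the next was on chromosome 2, 180300001 to 180400000, with 19 of 34 higher and none lower. On chromosome 3, 37900001 to 38000000, 17 of 38 loci were lower in the cultured arm and none higher. In human, 18 of 20 loci on chromosome 3, 170700001 to 170800000, were higher, in a window with no protein-coding gene assigned to the called loci. On chromosome 14, 61500001 to 61600000, 17 of 37 were higher, all assigned to PRKCH, a protein kinase C. The windows with the most lower loci in human were on chromosome 5, 138400001 to 138500000, with 16 of 61, of which 15 at EGR1, and on chromosome 14, 75200001 to 75300000, with 15 of 45 lower, all at FOS, and 2 higher.

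A few loci held most of the normalized counts. In human, 44 autosomal loci with a mean over 100000 held 84.1% of the summed means, and their median log2 fold change was 2.90 (SD 0.47 over loci). The strongest run of them, on chromosome 1 from 629417 to 634617, held 63.4% in 11 loci and lies over MTND1P23, MTND2P28, MTCO1P12, MTCO2P12, MTATP8P1, MTATP6P1 and MTCO3P12, nuclear pseudogenes of mitochondrial genes. Its log2 fold changes lay between 2.86 and 3.31, and 8 of the 11 loci passed the limits. In mouse, 92 such loci held 89.8% of the summed means, with a median log2 fold change of 0.87 (SD 1.28 over loci) and 25 called higher. Of these, 14 loci on chromosome 1 from 24611761 to 24615999 held 69.7% of the summed means, with log2 fold changes of 3.01 to 3.23, all 14 called higher in the cultured arm. Runs of 7 loci on chromosome 2 from 98662274 and of 32 loci on chromosome 9 from 3000535 had medians of 0.59 and 0.50, with none called.

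Accessibility at 10 days against 4 days, genes shared between human and mouse and sequence motifs were not analysed here, since they need values per library, a mouse annotation or a genome.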

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

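Centring, leaving out windows or weak loci and random lists were chosen after seeing the data. Counts of loci called higher stayed within 1.5 times the main count under every alternative run, from 27341 to 44630 in human and from 17001 to 31384 in mouse. Loci called lower in cultured cells were 21759 in human and 29429 in mouse at an adjusted p under 0.05 with no fold limit, against 11078 and 14473, by the wider limits; in human they were 4800 with fold changes centred on strong loci at gene edges, since that moves all fold changes up by 1.17. Under the other alternatives they lay between 8237 and 14327 in human and between 10159 and 14787 in mouse. Of the 19 lists, 2 were called, 1 with strong loci at gene edges centred on 0 and 4 against random lists. Immediate early genes were called under each, with adjusted p from 0.00014 to 0.0206. Immune markers had adjusted p of 0.122 on the locus with the highest mean and 0.061 with gene edges centred, and 0.0104 to 0.0486 under the others. Glucocorticoid targets, not called in the main test, had 0.0314 on the locus with the highest mean and 0.0076 against random lists, and 0.199 to 0.254 under the 3 centrings. HOX and limb genes had 0.00887 against random lists and 0.0672 to 0.138 under the others. For these lists the cause was not tested. The 32 human loci named as largest changes or at fixed genes kept their side of the limits with fold changes centred on the median and on the trend. With gene edges centred 30 did, while HEYL at -2.33 no longer passed and NOTCH3 at 3.90 did, since all fold changes move up. No paired analysis was possible because the tables hold no columns of libraries. For the same reason other normalizations, tests and filters, blocks by replicate, leaving out libraries, 3 groups in mouse and an estimated correlation were not run; promoter loci and mouse lists need an annotation, and motifs a genome, not used here. The weakest loci carry little: in the lowest of 10 bins of human loci by mean 7 of 19072 were called. In bins 4 and 5, 7.24% and 15.8% of loci were called higher and 3.44% and 5.92% lower. With loci under the median mean left out, 27341 of 32117 higher and 9002 of 11078 lower calls remained in human.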

Other observations

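The tests of explanations in this section were chosen after the data were seen. The limits of each, except the excess of immune loci, were written or rewritten after the values were seen. The genes and runs of the next 2 paragraphs were chosen after their values were seen. Several genes held many called human loci. KAZN had 41 of 97 loci higher in culture and 5 lower, NTM 40 of 129 and 7, KCNMA1, a potassium channel, 36 of 73 and 1, and NRG1 35 of 65 and 4. CREB5, a partner of AP-1 subunits, had 16 of 100 loci lower and 8 higher, BCL2, an inhibitor of cell death, 13 of 48 lower and 1 higher, and RUNX1 13 of 67 lower and 5 higher. NAV2 was among the genes with the most loci in both directions, 31 higher and 15 lower of 133.

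Dense runs of loci had few calls. In windows of 200 kb with at least 100 loci, 3.37% of tested human loci and 2.62% of mouse loci were called, against 23.6% and 19.2% elsewhere. The mouse run with the most loci, on chromosome 4 from 139740217 to 139880012, had 390 loci with 3 called and a median log2 fold change of -0.09. The run with the most loci in human, on chromosome 21 from 10640357 to 10814260, had 402 loci, 3 called and a median of -1.16.

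Well-covered loci over nuclear copies of mitochondrial genes, 40 with a mean over 1000, had a median log2 fold change of 2.90 (SD 2.09), of which 13 were called higher. All 136 loci at such copies had a median of 1.74 (SD 2.44). Reads of mitochondrial DNA placed on nuclear copies may account for it: 30 well-covered loci at such pseudogenes on chromosomes other than 1 had a median of 2.80 (SD 2.42), beside 3.09 in the chromosome 1 run. The authors' scaling cannot be told apart as a source: 6404 other strong autosomal loci, with means of 1000 to 100000, had a median of -0.13, but their SD was 3.64 and a normalization puts typical loci near 0 whatever the cells did. Whether cultured cells held more mitochondrial DNA or lost less of it in lysis was not tested.

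Immediate early genes were called lower in culture as a list. A tilt of fold changes with the mean count as the whole cause is argued against, since the adjusted p was 0.000355, still lower, with the trend removed. The list test compares genes with each other and says nothing about a shift common to all loci; with gene edges centred on 0, 71 loci of the list were lower and 55 higher. A response to tissue digestion and sorting was not excluded, and the test used could not have supported it. A state of resting cells before isolation would give the same high share of members lower in culture. The share was 65.2%, 15 of 23 members with more loci called lower than higher. It lay under the 75% set for either and over the 50% below which the response would be excluded. The share rests on calls, and KLF6, KLF2, NR4A2, MYC and IER3, with more loci called higher, had medians below 0. It also rests on giving loci to a gene from up to 50 kb away. At the 7 members with more called higher, the locus with the smallest p lay 10414 bp (KLF2) to 47056 bp (IER5) from the gene. The response cannot be told apart from a state of satellite cells in the muscle, since all fresh libraries were digested and sorted.

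Immune markers had 22 of 73 loci called higher in culture and 1 lower. Opening of loci away from gene edges in any gene is argued against, since 22 were called higher where context and mean count gave 8.78, an excess at percentile 99.9 of random lists. The test used could not decide on blood cells in the cultures. The share of members with more loci called higher than lower was 41.7%, 5 of 12, under the 75% set for this cause. That limit was set after the value was seen, and the 7 members with no call count against it although their loci are few. The share therefore does not speak against blood cells. No member had more called lower, but of the 7 with no call CORO1A, CCR2, ITGAM, CD68 and CD14 had medians below 0, from -2.53 to -0.68, and SPI1 and IRF8 had medians of 2.17 and 1.30. Blood cells cannot be told apart from opening in myoblasts themselves, since the loci of these 7 are few and not called. The cells were sorted before culture, by markers not known here, which could have removed blood cells. None of the immune genes is in another list.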
